A study of Homo sapiens with 79 samples.

How the data were processed

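The series holds ChIP-seq of BT549, an established triple-negative breast cancer cell line, with antibodies against the transcription factors GATA6, MYC and the glucocorticoid receptor (GR), the Mediator subunit MED1, and BRG1, the ATPase of the SWI/SNF chromatin remodelling complex that the gene SMARCA4 encodes. Per the labels, cells were treated with the synthetic glucocorticoid dexamethasone (DEX) at 500 nM for 2 or 4 h, with siRNA against GATA6 (siGATA6) or a control siRNA (siCtl) for 72 h, or with BRM014, an inhibitor of the BRG1 and BRM ATPases, at 10 µM for 4 h, and chromatin was crosslinked with DSG and formaldehyde. Of 79 samples in the labels, 43 have a peak list that was used here. The other 36, which are 21 inputs and 15 further ChIP samples, were not analysed here. GATA6 levels after knockdown were not measured by these files, so the knockdown could not be checked.

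Each of the 43 files is a narrowPeak list of 1 library, so peaks were called per library and not on pooled replicates. The deposited lists give the fold enrichment at the summit (a ratio) in column 7, −log10 of the p-value in column 8 and −log10 of the q-value in column 9. The lowest deposited −log10 q was 1.30142, which is a q-value threshold of 0.05. Per the submitters' processing notes, bcl2fastq, SAMtools, MACS2 and HOMER were used with the build GRCh38/hg38. Their versions, the aligner, the control used in peak calling and any filter are not given in the sources used here. The labels name a target number of read pairs per sample, but the depth reached is unknown, because the lists hold no read counts, so the number of peaks stands in for depth. A deeper or better enriched library gives a longer list, and a site missing from a list can hold signal just under the threshold. The fold and the −log10 p of a peak are the authors' own values and were used only to describe, rank or filter peaks within a list.

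Groups were taken from the labels. Each group had 3 libraries, except MYC and MED1 with DMSO or BRM014 and BRG1 with vehicle, which had 2. The labels call replicates biological but do not say how cultures were made, so p-values measure the spread between these samples. No lists were identical among 903 pairs of libraries. In each comparison the peaks of all libraries on the 22 autosomes, X and Y were merged into regions where they shared at least 1 bp. A region was gained if every library of the second group and none of the first had a peak there, lost in the reverse case, and kept if every library had one. If 6 libraries were grouped at random, a region called in 3 of them would be split cleanly in 10% of regroupings, so each count was set beside the highest count from any other split of the same libraries. The sites of a factor were regions called in all libraries of a group, namely 46806 for GR at 2 h (siCtl), 26570 for GR at 4 h (DMSO), 46001 for GATA6 and 35297 for MED1 (siCtl) with DEX, and 33783 for BRG1 with DEX. No GR library without DEX was used, so GR sites of vehicle-treated cells are unknown here.

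Peaks per library and shares of peaks at another factor's sites were compared with two-sided exact permutation tests. The smallest p is 0.1 for 3 against 3 or 2 against 3 libraries, 0.333 for 2 against 2, and 0.005 for the 12 MED1 libraries of the siRNA experiment, permuted within siRNA or treatment (400 arrangements). For these 12 libraries a two-sided Fisher's exact test per region was run on 6 against 6 libraries over the regions called in 5 to 7 of them, with Benjamini-Hochberg adjustment at 0.05. Classes of sites were compared by two-sided Fisher's exact tests and odds ratios with 95% intervals. Sites are not independent replicates, so these p-values and intervals describe the lists and not a population of cultures.

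No genome sequence was used, so the planned motif shares were not computed. Gene positions came from an NCBI RefSeq table of GRCh38.p14 with 20037 protein-coding genes and no strand. Sites were therefore described as within 1 kb of either end of a protein-coding gene, and genes by their span with 50 kb on each side, where the design had named transcription start sites. Genes named in the text followed a fixed rule. For each comparison these were the protein-coding genes nearest, within 100 kb, to the 10 gained and 10 lost regions with the best worst-case rank of −log10 p. For each gene list up to 4 members with the most lost, then most gained, regions were named. FKBP5, TSC22D3, PER1, DUSP1, SGK1, ZFP36, KLF9, GATA6, NR3C1, MYC, SMARCA4, SMARCA2, MED1, FOSL1 and JUN were looked up in every comparison. Some genes that the rule names are not reported here. A nearest gene is a position and not a target. The 14 lists were glucocorticoid-induced, glucocorticoid-repressed inflammatory, AP-1 subunits, GATA6 and endoderm, MYC targets, SWI/SNF subunits, TNBC growth and invasion, YAP-TEAD targets, cell cycle, epithelial, housekeeping, luminal breast, mesenchymal and other lineages. All 295 entries (293 distinct genes) were placed. The share of regions near list genes that were gained or lost was set against 10000 random sets matched on the number of regions, drawn for each gene from the 200 nearest in that number, two-sided, with adjustment over 280 tests.

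Alternatives set before the data were examined were peaks with −log10 q of 10 or more, lists shortened to the shortest list of a comparison, windows of 100 bp on each side of the summit, an overlap of at least 50% of the peak, the replicate number as a block, each library left out in turn, and 10 kb around genes. Added after the data were seen were a strict rule (−log10 q of 10 or more in every library of one group and no peak in the other), omission of DMSO replicate 1 or of siGATA6 replicate 2, comparisons within 20 bins of rank by the Mantel-Haenszel odds ratio, gained against lost sites, overlaps of gained or lost sites between factors, and the share of GR sites called. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. The calls were tested on simulated data with 200 planted regions per comparison. The gained rule recovered between 77% (MED1 with siGATA6, DEX against vehicle) and 87.5% (MYC and MED1 with BRM014), beside 488 (MED1 with vehicle, siGATA6 against siCtl) to 2203 (MED1 with BRM014) other regions gained or lost, each drawn at its own call rate over all libraries of the comparison. The 6 against 6 Fisher test recovered 0 of 200 planted regions in either comparison, because its smallest p of 0.00216 passes the adjustment only when at least 368 (DEX) or 371 (siGATA6) regions of the simulated data reach it. With 2000 planted it recovered 65.4% for DEX and 65.2% for siGATA6.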

Results

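Peak lists of 43 ChIP-seq libraries of BT549 cells were compared. They covered GATA6 with vehicle or 2 h of DEX, MED1 with siCtl or siGATA6 and vehicle or 2 h of DEX, GR after 2 h of DEX with siCtl or siGATA6, BRG1 with vehicle or 4 h of DEX, and GR, MYC and MED1 after 4 h of DEX with DMSO or BRM014. Lists held 14257 to 70477 peaks, and read depth is unknown. GATA6 libraries averaged 61520 ± 1404 peaks with vehicle and 66749 ± 3347 with DEX (SD, n = 3 each). MED1 libraries of the siRNA experiment averaged 46745 ± 2684 (siCtl vehicle), 50883 ± 2492 (siCtl DEX), 48130 ± 1983 (siGATA6 vehicle) and 47802 ± 2468 (siGATA6 DEX; n = 3 each). GR averaged 59508 ± 552 with siCtl and 55703 ± 5717 with siGATA6 at 2 h (n = 3 each). BRG1 averaged 35915 ± 305 peaks with vehicle (n = 2) and 45755 ± 2811 with DEX (n = 3). At 4 h, GR averaged 41123 ± 1397 with DMSO and 29513 ± 5145 with BRM014 (n = 3 each), MYC 30135 ± 5095 and 25836 ± 431, and MED1 27485 ± 3168 and 14302 ± 63.6 (n = 2 each). No difference in peaks per library passed adjustment over the 10 comparisons. The exact permutation p was 0.1, the smallest possible, for GATA6 (n = 3 against 3), BRG1 (2 against 3) and GR with BRM014 (3 against 3).

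**Figure D1:**
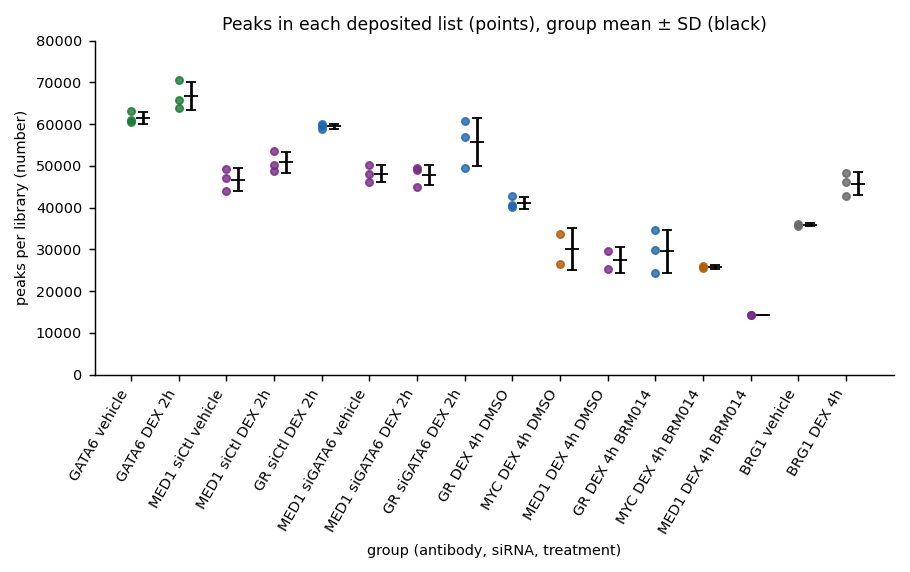
Number of peaks called in each library (points), with the mean and SD of each group (black). MED1 had 14257 and 14347 peaks with BRM014 against 25245 and 29725 with DMSO.

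The first comparison asked where GATA6, a zinc finger transcription factor, was called after 2 h of DEX. GATA6 gained 2578 sites, 5.69% of its DEX sites, and lost 684, while 37941 were kept. The best-ranked gained sites lay within ZBTB16 (chromosome 11, 114178591–114180326, fold enrichment 55.7 to 96.6 in the 3 DEX libraries), which encodes a zinc finger transcription factor, within ANXA13 (chromosome 8, 123689375–123691475), 23.6 kb from KLF9 (chromosome 9, 70438242–70439445, fold 30.3 to 47.3) and 12 kb from ANAPC16 (chromosome 10, 72247876–72249400). ATAD2, KCNMA1, PXYLP1, MIOS, ALDH7A1 and LPP were nearest to others. Around known glucocorticoid-induced genes, GATA6 gained 6 sites each at FKBP5, a co-chaperone of GR, at TSC22D3 and at FOXO3, 4 at BIRC3, 3 at KLF9, and 2 each at DUSP1 and SGK1. It gained 1 site near its own gene and 1 near FOSL1, and lost 1 near NR3C1, which encodes GR. None was gained or lost within 50 kb of PER1, ZFP36, MYC, SMARCA4, SMARCA2, MED1 or JUN. The best-ranked lost sites were weaker, such as one 35.2 kb from CDKN2B, an inhibitor of CDK4 and CDK6 (chromosome 9, 22044502–22045036, fold 6.90 to 9.66), with others nearest to DGKB, COL21A1, ME1, TSPAN2, GJC1, MAMLD1, CSMD3 and GBE1.

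GR sites took in 79.9% of the gained, 82.3% of the kept and 5.41% of the lost GATA6 sites, an odds ratio of gained against lost of 68.5 (95% interval 48.6 to 96.5, Fisher's exact p 1.52e-300). GR was called only in DEX-treated cells, so this ratio cannot separate GR from the treatment. The same ratio was 5.37 at BRG1 sites with DEX and 0.0557 at BRG1 sites with vehicle. MED1 sites of DEX-treated cells took in 61.6% of the gained GATA6 sites, and MED1 sites of vehicle-treated cells took in 8.11%. Gained and lost GATA6 sites were rarely within 1 kb of a gene end (5.04% and 3.51%, kept 27.2%), with an odds ratio of lost against kept of 0.0994 that was 0.0266 with −log10 q of 10 or more and 0.374 with summit windows. As a share of all peaks, GATA6 peaks at GR sites went from 61.1% ± 0.93 to 63.7% ± 3.3 (SD, n = 3 each), a difference within the spread (exact permutation p 0.3) that was 6.09 points at equal list lengths, 0.907 without DEX replicate 1 and 4.21 without DEX replicate 3. Of the GR sites themselves, 75.8% ± 0.52 carried a GATA6 peak with vehicle and 84.5% ± 2.5 with DEX (exact permutation p 0.1, the smallest possible, n = 3 each). Gained plus lost came to 3262 sites, against 878 in the highest other split of the 6 libraries. Under the strict rule 871 were gained and 43 lost. Gained sites numbered 4186 without DEX replicate 2, and lost sites 1284, 1542 and 1258 without vehicle replicates 1, 2 and 3, and 1046 and 1929 without DEX replicates 1 and 3.

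MED1, a Mediator subunit that marks active enhancers and promoters, was compared with vehicle after 2 h of DEX in both siRNA backgrounds. Over all 12 libraries MED1 calls rose at 2486 regions and fell at 696 (Fisher's exact test per region, Benjamini-Hochberg adjusted, smallest adjusted p 0.0125). At 1350 regions a peak was called in 6 of 6 DEX libraries and 0 of 6 vehicle libraries, and at 153 the reverse. Among the strongest of the former were a cluster 73.9 kb from VAPA (chromosome 18, 10033939–10053133, fold 127 to 271 in siCtl DEX libraries), a region 22 kb from KLF9 (chromosome 9, 70436666–70442631 in siCtl cells, fold 65.3 to 143), and regions nearest to LDLRAD3, N4BP2, VARS2, DDAH1, TFCP2L1, TRPM3 and GRAMD2B. Regions called with vehicle in 6 of 6 libraries and with DEX in 0 of 6 were nearest to FMO1 (chromosome 1, 171254737–171255468), SCAF8, HIBADH, CSMD3, POU1F1, SUCLG2, SIRPB1 and DIO2. GR sites took in 90.6% of the regions that rose and 19.0% of those that fell, against 53.3% of the 8699 regions tested. At GATA6 sites of vehicle-treated cells the order was the other way, with 9.86% of the regions that rose and 61.1% of those that fell, and at GATA6 sites of DEX-treated cells it was that of GR, with 53.3% and 38.9%.

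In siCtl cells MED1 gained 3668 sites and lost 1038. The best-ranked gained sites included one 37.4 kb from MET, the receptor of hepatocyte growth factor (chromosome 7, 116630925–116634768, fold 47.9 to 90.1), and others nearest to TTN, INPP5A, PTPRG, ELN and LAMA3. Of the genes looked up, FKBP5 gained 6, KLF9 4, TSC22D3 3, SGK1 2, and DUSP1, ZFP36 and GATA6 1 each, while SMARCA2 and JUN lost 1 each. Lost sites ranked best near ADK, CNTNAP5, MUSK, NAALADL2, RALYL, CDC42BPA, SMAD6, LRFN5, HDAC9 and CAMK2N1. In siGATA6 cells MED1 gained 2291 and lost 1411 sites, with ZBTB16 (chromosome 11, 114174713–114182695, fold 77.2 to 149), VAPA and KLF9 among the best-ranked gained and NALF1, PARD3B, FMO1, ANTXR1, ACSM6, UTRN and SFRP1 among the lost. FKBP5 gained 8 sites there, KLF9 3, and TSC22D3 and SGK1 2 each. In siCtl cells 84.6% of gained and 22.4% of lost MED1 sites were at GR sites (odds ratio 19.0, 95% interval 16.0 to 22.5), and in siGATA6 cells 84.3% and 22.7% (18.2, 15.4 to 21.5). Kept MED1 sites were at GR sites more often than gained ones, in 91.8% of cases in siCtl and 90.8% in siGATA6 cells (odds ratio of gained against kept 0.487 and 0.543). MED1 sites gained in siCtl cells coincided with GATA6 sites gained with DEX in 26.2% of cases (960 of 3668), against 1.47% of kept sites (odds ratio 23.7, 95% interval 21.0 to 26.9).

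The share of MED1 peaks at GR sites rose from 67.9% ± 1.8 to 73.5% ± 1.6 (SD, n = 6 each, exact permutation p 0.005, the smallest possible, adjusted 0.03). It was 4.39 percentage points higher with DEX in siCtl and 6.81 points in siGATA6 cells, a difference of 2.42 points that was within the spread (exact permutation p 0.22, n = 3 per group), was 1.38 and 1.5 points without vehicle replicate 2 of siCtl or siGATA6, and turned to −2.53 at equal list lengths. Of the GR sites themselves, MED1 was called at 70.5% ± 3.4 with vehicle and 82.3% ± 4.5 with DEX in siCtl cells, 11.8 points more, and at 71.7% ± 2.2 and 78.2% ± 4.3 in siGATA6 cells, 6.49 points more (SD, n = 3 each, exact permutation p 0.1 each, the smallest possible). By this measure the effect of DEX was the smaller in siGATA6 cells, by −5.27 points, also within the spread (exact permutation p 0.245, n = 3 per group). On regions merged over the 12 libraries, DEX gained 3520 sites in siCtl and 2027 in siGATA6 cells, a difference of −1493 with an exact permutation p of 0.065 (adjusted 0.26, n = 3 per group). Of these, 1350 were gained in both, where independent lists would share 89.2. The highest other split gave 545 gained plus lost sites in siCtl cells (real 4706) and 540 in siGATA6 cells (real 3702). Requiring −log10 q of 10 or more gave 2127 gained and 608 lost sites in siCtl and 1392 gained in siGATA6 cells, and 1574 regions up and 462 down over all 12 libraries. The strict rule gave 1288 gained and 86 lost in siCtl and 785 gained and 158 lost in siGATA6 cells. In siCtl cells lost sites numbered 1728, 2472 and 1622 without vehicle replicates 1, 2 and 3, and 1686 without DEX replicate 3. In siGATA6 cells gained sites numbered 3801 without DEX replicate 2, and lost sites 3125 and 2243 without vehicle replicates 1 and 3 and 2131 without DEX replicate 1. Over all 12 libraries, leaving out any of the 6 vehicle libraries, any siCtl DEX library or siGATA6 DEX replicate 3 gave 1379 to 1456 regions up and 175 to 277 down.

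**Figure D2:**
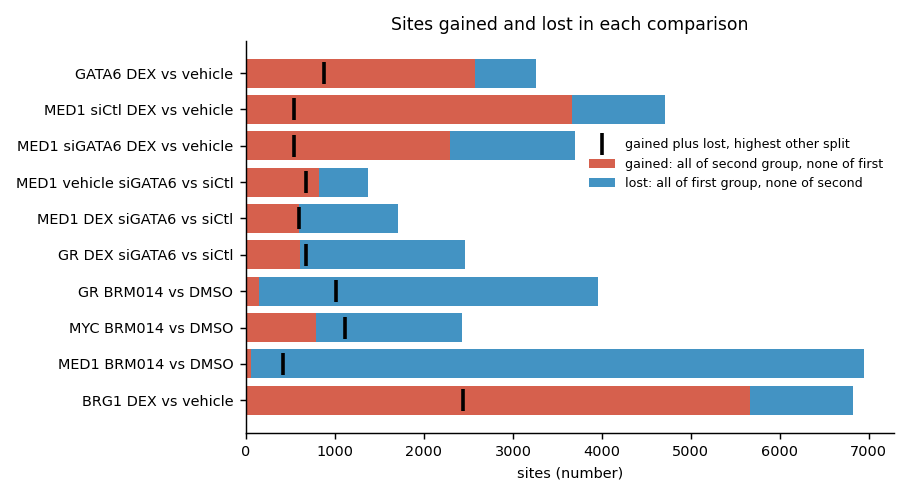
Stacked bars give the number of sites gained and lost in each comparison, and the black tick the gained plus lost sites of the highest other split of the same libraries. GATA6 with DEX had 3262 against 878, and MED1 with BRM014 6940 against 412.

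BRG1 was compared after 4 h of DEX. It gained 5660 sites, 16.8% of its DEX sites, and lost 1165. The best-ranked gained sites were nearest to PTPN1, a tyrosine phosphatase (chromosome 20, 50415043–50416663, fold 34.5 to 44.6), RPL13, ANAPC16, MIOS, CYTH3 and NFIC, or lay at FOXO3 (chromosome 6, 108653720–108655165, fold 22.3 to 28.7), ZBTB16 (chromosome 11, 114178549–114180932, fold 20.9 to 28.4) and LTBP1, which encodes a latent TGF-β binding protein (chromosome 2, 33152701–33154669, fold 17.4 to 24.8). PER1, a core clock gene, gained 5 BRG1 sites, FKBP5 and TSC22D3 4 each, ZFP36 and GATA6 3 each, KLF9, NR3C1, SMARCA2, MED1, FOSL1 and JUN 2 each, and DUSP1 and SGK1 1 each. Lost sites ranked best near ANKRD36C, NUP54, TINAG, INSYN2B, NDFIP2, FSIP2, LINGO2, USP46, COL12A1 and SLIT3. Unlike sites gained by GATA6 or MED1, sites gained by BRG1 lay within 1 kb of a gene end more often than kept ones (33.9% against 21.1%, odds ratio 1.91, 95% interval 1.80 to 2.04), and lost ones less often (2.23%, odds ratio 0.0868, but 0.247 with −log10 q of 10 or more, 0.244 at equal list lengths and 0.611 with summit windows). At equal rank in the DEX lists the direction for gained BRG1 sites turned. The Mantel-Haenszel odds ratio of gain at gene ends was then 0.869 (95% interval 0.812 to 0.931).

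Of gained BRG1 sites 50.7% were at GR sites of 4 h, against 2.06% of lost and 75.5% of kept sites (gained against lost, odds ratio 47.9, 95% interval 32 to 71.8). GR was called only in DEX-treated cells, so this ratio cannot separate GR from the treatment. Compared at equal rank in the DEX lists, BRG1 sites at GR sites had a Mantel-Haenszel odds ratio of gain of 0.910 (95% interval 0.853 to 0.971). Without ranking, 12.4% of them and 26.1% of the other BRG1 sites were gained. MED1 sites of siCtl cells after 2 h of DEX took in 77.8% of gained, 8.24% of lost and 85.6% of kept BRG1 sites, and GATA6 sites after 2 h of DEX 77.5%, 40.7% and 94.4%. The 19407 MED1 sites of 4 h (DMSO), the time of the BRG1 libraries, took in 46.2% of gained and 1.55% of lost BRG1 sites. A BRG1 peak was called at 73.9% ± 0.011 of GR sites with vehicle (SD, n = 2) and 91.2% ± 1.3 with DEX (n = 3, exact permutation p 0.1, the smallest possible). The share of BRG1 peaks at GR sites was 59.5% ± 0.68 (n = 2) and 56.3% ± 2.8 (n = 3), a difference within the spread (exact permutation p 0.3) that turned from −3.17 to 5.27 points at equal list lengths, and was −0.272 with −log10 q of 10 or more and −1.92 without DEX replicate 3. The highest other split gave 2441 gained plus lost sites (real 6825). Lists of equal length gave 3227 gained and 2214 lost sites, summit windows 1940 lost, the strict rule 1397 gained and 239 lost, and omission of vehicle replicate 1 or 2 gave 2846 or 3207 lost.

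**Figure D3:**
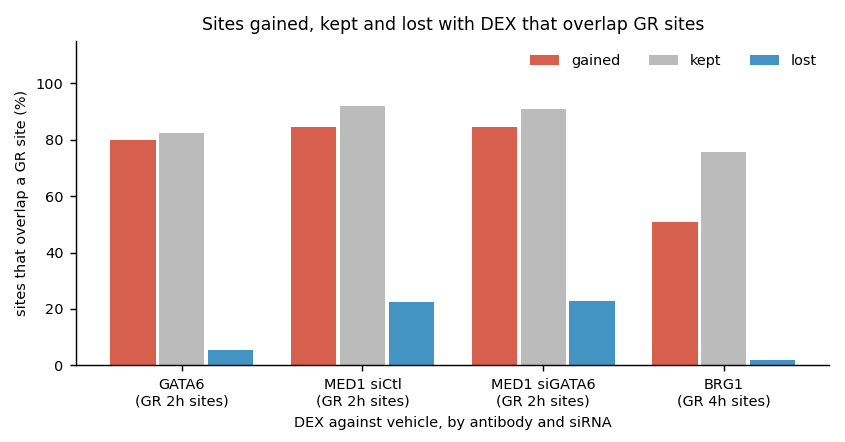
Percent of gained, kept and lost sites that lay at GR sites, for GATA6 and MED1 (GR at 2 h) and BRG1 (GR at 4 h), with DEX against vehicle. Gained sites were at GR sites in 79.9% (GATA6), 84.6% and 84.3% (MED1) and 50.7% (BRG1) of cases, and lost sites in 2.06% to 22.7%.

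Genes known to be induced by glucocorticoids had more gained sites than matched random genes in all 4 of the DEX comparisons. Around these genes GATA6 gained 20.1% of its sites (46 of 229, at 17 of 29 genes, random median 5.58%, adjusted permutation p 0.0187). MED1 gained 33.3% in siCtl cells (57 of 171, at 20 of 30 genes, random median 8.19%) and 25.8% in siGATA6 cells (42 of 163, at 15 of 29, random median 5.52%), both with an adjusted permutation p of 0.0187. BRG1 gained 36.7% (69 of 188, at 21 of 29, random median 22.3%, adjusted permutation p 0.0280). The raw p of the first 3 was 0.0002, the smallest that 10000 random sets can give. FKBP5 (chromosome 6, 35573590–35728583) went from 3 to 4 GATA6 peaks per library to 13 to 19, from 3 to 4 MED1 peaks to 15 to 19 in siCtl cells, from 4 to between 17 and 20 in siGATA6 cells, and from 1 BRG1 peak to 10 to 12, counted within 50 kb. A GATA6 site gained within the gene span (35722113–35723144, fold 18.4 to 29.6) overlapped a gained BRG1 site (35721548–35730714, fold 16.5 to 21.1). FOXO3 gained 9 MED1 sites in siCtl cells and 8 BRG1 sites, NFKBIA, the inhibitor of NF-κB, 6 MED1 sites in siCtl cells, BIRC3 5 MED1 sites in either siRNA background, ZBTB16 6 MED1 sites in siGATA6 cells and 8 BRG1 sites, and ERRFI1 7 BRG1 sites. Of 280 tests over the 14 lists, these 4 passed adjustment and no other did.

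**Figure D4:**
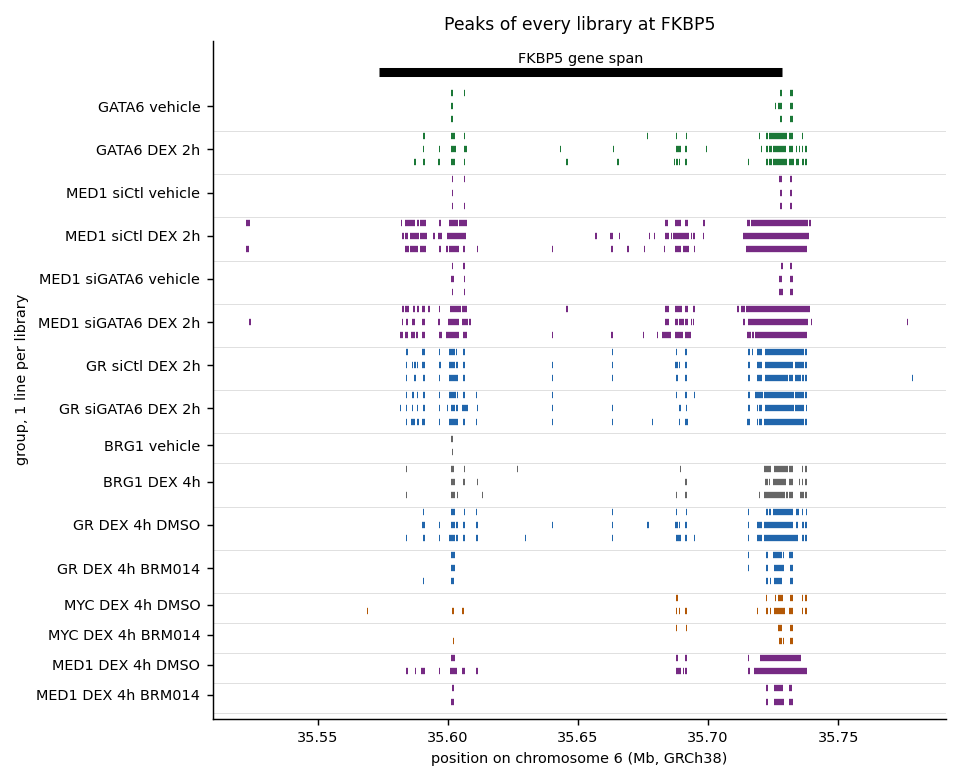
Peaks called in each library (bars, 1 line per library) along chromosome 6 around FKBP5, whose span is 35573590–35728583. BRG1 had 1 peak per library with vehicle and 10 to 12 with DEX, and GR 14 to 18 with DMSO and 5 to 6 with BRM014.

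Knockdown of GATA6 was compared with siCtl for MED1 and GR. GR lost 1854 sites, 4.0% of its siCtl sites, and gained 607. The best-ranked lost GR sites were strong ones, 84.1 kb from HAS2, a hyaluronan synthase (chromosome 8, 121526754–121527992, fold 57.6 to 71.3), 86 kb from ZC3H11B (chromosome 1, 219699058–219700633, fold 55.2 to 83.3) and within DPYD (chromosome 1, 97270605–97271809, fold 47.6 to 75.2), with others nearest to DGKB, MOSPD1, ACP3, PLCXD3, ADGRV1 and ITPK1. Most lost GR sites were weak, with a median rank 81.6% of the way down the siCtl lists, against 47.5% for all siCtl sites (worst rank over the 3 libraries). TSC22D3, ZFP36, GATA6, NR3C1 and JUN each lost 1 GR site, and ARID1A, ARID1B, ROR1, ASAP1 and RELB lost 2 each. MED1 with DEX lost 1110 and gained 596 sites, and its best-ranked lost sites were again near HAS2 (chromosome 8, 121526088–121527996), ZC3H11B, MOSPD1 and DPYD (chromosome 1, 97270437–97271951), with others near SBSPON, THNSL1, ARHGAP26, ROR1 and ARSB. MED1 with vehicle lost 542 sites and gained more than it lost (1368 gained plus lost), the best-ranked lost ones near MOSPD1 (chromosome X, 134943591–134952034, fold 20.2 to 34.2), ARSB (chromosome 5, 78926335–78929008), ADAMTS3, PALS1, ZC3H11B, FHIP1A, ATP8B1 and ROR1, a receptor tyrosine kinase-like protein. Gained sites ranked best near MSRA, RIMS2, TRIML2, SLC25A13 and VAV3 for GR, near LINGO2, CTAG1A, EIF2B2, MCU and C9orf72 for MED1 with DEX, and near ADAM32, ARHGEF37, LHX2 and SLC9A9 for MED1 with vehicle.

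Where GR sites lost with siGATA6 had a MED1 site in DEX-treated siCtl cells, MED1 was lost there too in 46.8% of cases (227 of 485), against 0.704% at kept GR sites (218 of 30960; odds ratio 124, 95% interval 99.1 to 155). This overlap was not compared at equal rank. Lost MED1 sites were weak too, with a median rank of 81.2% against 43.2% for all MED1 sites of siCtl cells with DEX, so weakness in both lists stays open. Lost sites were more often at GATA6 sites than gained ones, with 55.9% against 10.9% for GR, 60% against 30.7% for MED1 with DEX and 70.5% against 28.8% for MED1 with vehicle, but less often than kept ones, with 82.5%, 91.1% and 91.8%. Of GATA6 sites, 84.7% ± 1.0 carried a GR peak with siCtl and 78.8% ± 4.2 with siGATA6 (SD, n = 3 each, exact permutation p 0.1, the smallest possible), a difference of −5.95 points that was −3.52 without siGATA6 replicate 2. The share of GR peaks at GATA6 sites was 68.4% ± 0.49 and 68.6% ± 4.0 (n = 3 each, exact permutation p 0.9), and that of MED1 peaks 71.4% ± 2.4 and 71.3% ± 1.8 (n = 6 each, exact permutation p 0.95), and neither difference kept its sign in all alternatives. Over the 12 MED1 libraries 0 regions passed Fisher's exact test with Benjamini-Hochberg adjustment for siGATA6, and 580 had an unadjusted p under 0.05. The smallest p passes that adjustment only when at least 377 regions reach it. It was reached by 56 regions called in 6 of 6 siGATA6 and 0 of 6 siCtl libraries and by 114 the other way. The highest other split gave 674 gained plus lost sites for GR (real 2461), 599 for MED1 with DEX (real 1706) and 669 for MED1 with vehicle (real 1368). Simulated libraries with no difference outside the planted regions gave 288 gained and 299 lost GR sites. All simulated libraries were drawn alike, without the differences in list length of the real ones, so these counts are no baseline for the real gains and losses.

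The GR result rested partly on siGATA6 replicate 2, which had the shortest list (49452 peaks, the others 56990 and 60667). Without it GR gained 1579 and lost 2016 sites. Lost GR sites numbered 2801 and 2810 without siCtl replicates 1 and 3 and 3257 without siGATA6 replicate 3, and gained ones 974 and 1002 without siCtl replicates 1 and 2 and 1038 and 914 without siGATA6 replicates 1 and 3. For MED1 with DEX, lost sites numbered 2215, 2067 and 1731 without siCtl replicates 1, 2 and 3 and 1944 without siGATA6 replicate 3. Gained ones numbered 1087 without siCtl replicate 3 and 1062, 1206 and 1023 without siGATA6 replicates 1, 2 and 3. For MED1 with vehicle, gained sites numbered 1354 and 1640 without siCtl replicates 1 and 3 and 2023 and 1359 without siGATA6 replicates 1 and 3, and lost ones 1058, 1367 and 851 without siCtl replicates 1, 2 and 3. The strict rule left 592 lost and 111 gained GR sites, 153 and 70 MED1 sites with DEX, and 96 and 107 with vehicle, and −log10 q of 10 or more left 556 and 259 lost MED1 sites.

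BRM014 was set against DMSO in cells given DEX for 4 h, to ask which GR, MYC and MED1 sites were still called when the BRG1 and BRM ATPases were inhibited. GR lost 3811 sites (14.6% of its DMSO sites) and gained 141. MED1 lost 6883 (35.8%) and gained 57, and MYC lost 1633 (7.61%) and gained 789. The best-ranked lost GR sites were 7.6 kb from LMX1A (chromosome 1, 165364360–165365616, fold 29.5 to 82.7) and within P4HA2, a collagen prolyl hydroxylase (chromosome 5, 132214771–132216021, fold 14.9 to 82.8), with others nearest to ABRA, NTRK3, NME7, PAPPA, GEM, PLCL1, ANO10 and MLIP. FKBP5 lost 7 GR sites, 3 MED1 and 3 MYC sites, and the GR peaks called there went from 14 to 18 per library to 5 to 6. TSC22D3 and DUSP1 lost 2 GR sites each (TSC22D3 at chromosome X, 107700063–107700963, fold 5.91 to 45.4), SGK1 and KLF9 1 each, CRISPLD2, RUNX2 and GRHL2 4 each, and DDIT4, MT1X, EPAS1, ETS1, ESR1 and CA12 3 each. MED1 lost sites 25.9 kb from CHD7, 49 kb from SKOR1 and within ARFRP1, ZBED4, FAM186B, FCN2, EEFSEC, YIF1B and LTBP1 (chromosome 2, 33152628–33154623), the last overlapping a BRG1 site gained with DEX. ERRFI1 lost 7 MED1 sites, ZBTB16 and ASAP1 5 each, ANGPTL4, RUNX2, GADD45A and TGFB1 4 each, MET, JUNB and CCND1 3 each, and PER1, SGK1 and FOSL1 2 each. MYC lost sites near HECW1, BCAR3, KCNT2, ITCH, PLXNB1, BPNT2, KIF5B, PGAP6, ETS1 (chromosome 11, 128582504–128583401) and ARMC12 (chromosome 6, 35737083–35737943, 8.5 kb from FKBP5), and gained them near PRSS3, C1QTNF8, TRAPPC9, SIM1, VRTN and PTGES2. The few gained GR sites ranked best near MNAT1, AFG2A, HS3ST1, PDLIM2 and E2F4, and gained MED1 sites near SLC17A9, UBN2, TTC8, SYNC and CXCL2.

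Lost sites lay less often near gene ends than kept ones. Within 1 kb of a gene end were 4.28% of lost and 36.9% of kept GR sites (odds ratio 0.0766, 95% interval 0.0653 to 0.0898), 11.8% and 54.4% of MYC sites (0.112, 0.0959 to 0.130, and 0.241 with summit windows), and 35.5% and 52.8% of MED1 sites (0.492, 0.461 to 0.524, and 0.748 with −log10 q of 10 or more). BRG1 sites with DEX took in 74.8% of lost and 92.2% of kept GR sites (odds ratio 0.251, 95% interval 0.229 to 0.275, Fisher's exact p 5.78e-175; 0.562 with −log10 q of 10 or more and 0.781 with summit windows), 72.8% and 95.1% of MED1 sites, and 76.3% and 80.5% of MYC sites. At equal rank in the DMSO lists, the Mantel-Haenszel odds ratio of loss at BRG1 sites was 0.693 (95% interval 0.635 to 0.755) for GR. It was 0.380 (0.348 to 0.416) for MED1 but 1.81 (1.59 to 2.06) for MYC, the other way. Over all GR sites, MED1 was lost at 7.29% of lost and 19.4% of kept ones (odds ratio 0.327, 95% interval 0.288 to 0.371, and 0.178 with −log10 q of 10 or more). Among GR sites where MED1 was called with DMSO, it was lost at 85.3% of lost sites (278 of 326) and 23.6% of kept ones (odds ratio 18.6, 95% interval 13.7 to 25.3), and MYC, in the same way, at 45.7% (166 of 363) and 5.07% (15.8, 12.7 to 19.7). These overlaps were not compared at equal rank. Lost sites ranked lower than all DMSO sites (median 72.1% against 50.7% for GR, 69.0% against 47.5% for MED1, 81.4% against 46.4% for MYC), so weakness in both lists stays open. Over all GR sites MYC was lost at 4.36% of lost and 3.90% of kept ones (odds ratio 1.13, Fisher's exact p 0.199), a ratio that went to 0.764 with −log10 q of 10 or more, 0.785 with summit windows and 1.34 with equal list lengths. Sites where MED1 had been gained after 2 h of DEX in siCtl cells were lost more often than those where it had been kept, for MED1 (72.2%, 270 of 374, against 33.8%), GR (30.9%, 481 of 1556, against 9.50%) and MYC (32.9%, 26 of 79, against 6.38%). Where BRG1 had been gained with DEX the same held for MED1 (44.9% against 27.4%, odds ratio 2.16) and, by less, for GR (17.7% against 11.8%, 1.61), while MYC was lost less often than where BRG1 had been kept (4.31% against 8.51%, 0.486, 95% interval 0.394 to 0.601). At equal rank the BRG1 ratio was 2.04 for MED1 and 1.12 for GR. The MED1 contrast was not compared at equal rank. MED1 sites gained with DEX were weak, with a median rank of 67.9% down the siCtl DEX lists against 43.0% for all sites there, so weakness stays open for their loss.

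**Figure D5:**
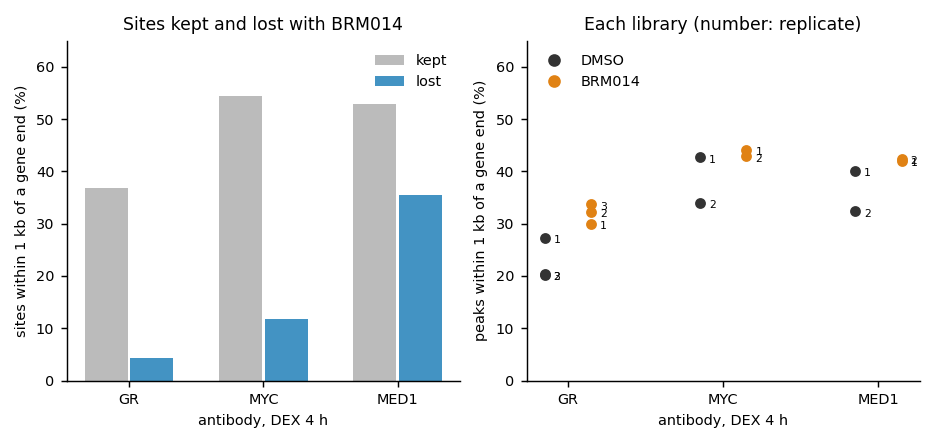
Left, percent of kept and lost sites within 1 kb of a gene end for GR, MYC and MED1 with BRM014 against DMSO. Right, percent of each library's peaks there, with the replicate number, where DMSO replicate 1 had 27.3% (GR), 42.7% (MYC) and 40.1% (MED1) against 20.2% and 20.3%, 34.1% and 32.4% in the other DMSO libraries.

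DMSO replicate 1 had a higher share of peaks near gene ends than any other DMSO library for all 3 factors, with 27.3% of GR, 42.7% of MYC and 40.1% of MED1 peaks. For MYC and MED1 there was only 1 other DMSO library. The corresponding ranges with BRM014 were 30.0% to 33.7%, 42.9% to 44.1% and 42.0% to 42.5%. Without it GR lost 10254 sites and gained 1198, MYC lost 9751 and gained 1525, and MED1 lost 15539 and gained 343. Lost sites were then near gene ends in 3.07% (GR), 7.04% (MYC) and 20.3% (MED1) of cases and kept ones in 36.5%, 53.0% and 51.2%, and the MED1 odds ratio went from 0.492 to 0.243. BRG1 sites then took in 61.8% of lost and 92.1% of kept GR sites (odds ratio 0.139, against 0.251), 70.1% and 94.6% of MED1 sites, and 77.0% and 79.8% of MYC sites. At equal rank the odds ratio of loss at BRG1 sites was then 0.328 for GR and 0.486 for MED1 but 2.90 for MYC. For MED1 and MYC this leaves 1 DMSO library. GR gained 264, 314 and 789 sites without BRM014 replicates 1, 2 and 3 and lost 5748 without BRM014 replicate 1. MYC lost 3268, 2573 and 2754 and gained 1585, 3301 and 2974 without DMSO replicate 2, BRM014 replicate 1 and BRM014 replicate 2, and MED1 gained 96, 656 and 812 and, without DMSO replicate 2, lost 11434. Gained plus lost sites came to 3952 for GR, 2422 for MYC and 6940 for MED1, against 1016, 1109 and 412 in the highest other split. In simulated libraries with no difference outside the planted regions, gained and lost sites numbered 340 and 333 for GR, 814 and 899 for MYC and 1079 and 1124 for MED1. Regions lost with BRM014 entered the simulation at their call rate over DMSO and BRM014 libraries together, which adds simulated gains. The simulation is therefore no baseline for gained sites, and for MED1 it exceeded the 412 of the highest other split. Its libraries were also drawn alike, without the real differences in list length, so it is no baseline for lost sites either. Lists of equal length gave 1620 lost and 918 gained GR sites and 1696 lost and 613 gained MED1 sites, and the strict rule 1164 and 10 for GR, 2138 and 0 for MED1, and 162 and 29 for MYC. With −log10 q of 10 or more MYC lost 966 and gained 313 sites and MED1 gained 5, and summit windows gave 389 gained GR, 1191 gained MYC and 698 gained MED1 sites.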

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

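The strict rule was chosen after the results were seen, and the other alternatives were planned. Of 450 alternative values 308 kept the direction and side of the threshold of a tested result or lay within 1.5 times a reported count, 124 counts moved further, 17 values changed direction and 1 passed the threshold anew. The gene-end odds ratios of lost against kept sites, the odds ratio of lost GR sites at BRG1 sites (0.562 with −log10 q of 10 or more, 0.262 at equal list lengths and 0.781 with summit windows, against 0.251) and the 4 gene list calls (also 4 within 10 kb of the genes) kept their direction and call in each alternative run for them, though the odds ratios changed in size. Among shares and peaks per library, values that had not passed a test changed sign. At equal list lengths the MED1 interaction at GR sites was −2.53 points, the GR share at GATA6 sites with siGATA6 −2.15 and the BRG1 share at GR sites with DEX 5.27. The GR share was −0.616 with −log10 q of 10 or more, and the MED1 share at GATA6 sites 0.415 with 50% overlap. Leaving out libraries gave −0.647 to 0.375 points for that MED1 share, −1.87 to 2.15 for the GR share, and −2.68% to 2.26% and −0.0982% to 5.74% for peaks per MED1 library (DEX in siGATA6 cells, and siGATA6 with vehicle). Peaks with −log10 q of 10 or more left 2127 gained and 608 lost MED1 sites for DEX in siCtl and 1392 gained in siGATA6 cells, 259 and 556 MED1 sites lost with siGATA6 under vehicle and DEX, 313 gained and 966 lost MYC sites and 5 gained MED1 sites with BRM014, and 1574 MED1 regions up and 462 down over both siRNAs. Equal list lengths gave 918 gained and 1620 lost GR and 613 gained and 1696 lost MED1 sites with BRM014, and 3227 gained and 2214 lost BRG1 sites. Summit windows gave 389 gained GR, 1191 gained MYC and 698 gained MED1 sites with BRM014, 1940 lost BRG1 sites and 1107 MED1 regions down with DEX over both siRNAs. The strict rule, which asks for more by its construction, gave gained and lost sites of 871 and 43 (GATA6), 1288 and 86 (MED1 with DEX, siCtl), 785 and 158 (siGATA6), 107 and 96 (MED1 siGATA6, vehicle), 70 and 153 (DEX), 111 and 592 (GR siGATA6), 10 and 1164 (GR with BRM014), 29 and 162 (MYC), 0 and 2138 (MED1) and 1397 and 239 (BRG1). The odds ratio of MYC loss at lost GR sites went from 1.13 to 0.764 (exact Fisher p 0.0163) with −log10 q of 10 or more and 0.785 (p 0.00813) with summit windows, both reversed, and to 1.34 (p 0.0168) at equal list lengths. The cause was not tested, except where a stricter rule leaves fewer peaks. Leaving out each library loosens the gained and lost rules, and gave gained and lost ranges of 3022 to 4186 and 937 to 1929 (GATA6), 3895 to 5245 and 1332 to 2472 (MED1 with DEX, siCtl), 2483 to 3801 and 1767 to 3125 (siGATA6), 996 to 2023 and 683 to 1367 (MED1 siGATA6, vehicle), 839 to 1206 and 1317 to 2215 (DEX), 893 to 1579 and 2016 to 3257 (GR siGATA6), 164 to 1198 and 3941 to 10254 (GR with BRM014), 1525 to 3301 and 2573 to 9751 (MYC), 96 to 812 and 8471 to 15539 (MED1), 6766 to 8044 and 1370 to 3207 (BRG1), and 1379 to 3318 up and 175 to 915 down for MED1 with DEX over both siRNAs, where the smallest p also rises with fewer libraries. Same-numbered replicates deviated together only weakly (correlations −0.0124 to 0.118, in no comparison all over 0.1), so the numbers were not taken to pair samples. With the replicate block the MED1 regions over both siRNAs were 1350 up and 153 down with DEX, and 56 and 114 with siGATA6, where the reported count was 0, and no other call changed. Every sample correlated best with its own number for GATA6 with DEX, for MED1 with DEX in either siRNA background and for GR with siGATA6, a hint from the data and not the design. The planned motif shares, with their 50 bp alternative, were not run, because no genome sequence was used. Unknown depth limits every loss, since a missing peak is not a missing signal.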

Other observations

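The tests on unequal list lengths, on more peaks in the DEX libraries, on MED1 sites with and without BRG1, on gained or lost overlaps between factors, without DMSO replicate 1 at equal rank and on splits of the libraries were chosen after the results they bear on were seen, and for siGATA6 over 12 MED1 libraries the count was chosen after 0 regions had passed adjustment. The gene-end predictions preceded the tests at equal rank, but the gene-end shares without ranking had been seen. Of 280 list tests 20 had an unadjusted permutation p under 0.05, the 4 adjusted calls included. Near glucocorticoid-repressed inflammatory genes MED1 lost 8.33% of sites in siCtl cells with DEX (6 of 72, random median 1.39%, p 0.0112, adjusted 0.30), namely 2 at LIF, which encodes a cytokine, and 1 each at CCL2, CXCL8 and IL1A among others. GATA6 sites near the same list were lost in 3.96% (p 0.0272), at CXCL3, CXCL8, IL6 and LIF. Near mesenchymal genes BRG1 gained 12.6% of sites (19 of 151, random median 21.7%, p 0.0088, adjusted 0.30) and GATA6 1.09% (p 0.0192), and near TNBC growth and invasion genes BRG1 gained 12.9% (22 of 171, random median 21.6%, p 0.0166, adjusted 0.387). With BRM014, GR lost 20.3% of sites near glucocorticoid-induced genes (35 of 172, random median 11.1%, p 0.0040, adjusted 0.224) and 27.6% near luminal breast genes (8 of 29, p 0.0098, adjusted 0.30), and MYC lost 13.2% near YAP-TEAD targets (12 of 91, random median 5.49%, p 0.0118, adjusted 0.30), with 2 sites each at LATS2 and CRIM1.

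For the other lists the smallest unadjusted permutation p was 0.0374 for GATA6 and endoderm genes (GR lost with siGATA6, 4 of 38 sites, at EOMES, DKK1 and GATA6), 0.0288 for MYC targets (GATA6 gained with DEX, 1 of 130, at ODC1), 0.0584 for AP-1 subunits (MED1 gained with DEX in siGATA6 cells, 1 of 85), 0.0984 for SWI/SNF subunits (MED1 lost with siGATA6 and vehicle, 3 of 89), 0.0864 for cell cycle genes (GATA6 gained with DEX, 1 of 98, at CDK6), 0.115 for epithelial genes (GATA6 lost with DEX, 3 of 99), 0.118 for housekeeping genes (MED1 gained with BRM014, 1 of 37) and 0.0618 for other lineages (MED1 lost with DEX in siCtl cells, 3 of 33). BRG1 sites gained with DEX were at MYC sites in 44.8% of cases, lost ones in 1.37% and kept ones in 52.2% (odds ratio of gained against kept 0.742). BRG1 and GATA6 gained the same places in 9.20% of gained BRG1 sites (521 of 5660) and 0.205% of kept ones. Of the genes looked up, MYC gained 2 sites with BRM014 at ZFP36 and 1 each at SGK1, GATA6, NR3C1 and SMARCA4, and lost 1 each at SGK1, GATA6, TSC22D3 and FOSL1 and 3 at FKBP5. Over whole lists DMSO replicate 1 overlapped the BRM014 libraries slightly more than the other DMSO libraries for GR (mean Jaccard index 0.575 and 0.557) and MYC (0.623 and 0.607), and less for MED1 (0.553 and 0.641). At FKBP5 it had 14 GR peaks, against 5 to 6 with BRM014, 5 MED1 peaks (the other DMSO library 12, BRM014 4 each) and 7 MYC peaks (13, and 4 each).

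Sites no longer called with BRM014 lay less often near gene ends than kept ones, though 35.5% of lost MED1 sites were there. Loss of calls by weakness alone, with shorter BRM014 lists, would spare gene ends only as far as rank does, yet at equal rank GR sites at gene ends had far lower odds of loss (Mantel-Haenszel odds ratio 0.0557, 95% interval 0.0467 to 0.0664, and 0.0474 without DMSO replicate 1). For MED1 the same ratio was 0.717 (0.667 to 0.770), an estimate within the bounds set beforehand for loss by rank. It was 0.278 (0.262 to 0.296) without DMSO replicate 1, which leaves 1 DMSO library. Fewer called peaks therefore remain an open explanation for MED1. At equal rank, however, MED1 sites with BRG1 had an odds ratio of loss of 0.380 (0.348 to 0.416), which rank alone does not give. At equal list lengths gained plus lost sites came to 2538 for GR and 2309 for MED1, 3.85 and 3.93 times the highest other split (659 and 588). These sums argue against unequal lengths as the source of every difference, though 10 splits (GR) and 3 (MED1) are too few for a share under 0.05. They do not test the excess of loss. Lost sites were then fewer and gained sites more numerous than in the full lists, so shorter BRM014 lists stay open for part of that excess. GR loss at equal rank was slightly greater where DEX had brought BRG1 in (odds ratio 1.12, 1.00 to 1.26), which argues only against odds over 1.5 times higher there. MED1 gave 2.04 (1.82 to 2.29). A greater dependence of distal GR sites on the ATPases is a hypothesis that the design allows. Yet GR sites with BRG1 had lower odds of loss at equal rank than those without (0.693, 0.635 to 0.755, and 0.328 without DMSO replicate 1). DMSO replicate 1, whose omission takes lost GR sites from 3811 to 10254, and the unknown depth and enrichment of each library stay open.

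MED1 sites gained with DEX lay at GR sites. Longer DEX lists as the whole source are argued against by siGATA6 cells, where peak numbers differed by −0.681% (−2.68% to 2.26% with a library left out) and gained sites still exceeded lost ones at GR sites by 61.5 percentage points. Strong open sites shared by both factors whatever the treatment are argued against at equal rank, where sites at GR sites had an odds ratio of gain of 2.10 (1.88 to 2.35), although without ranking 10.4% of MED1 sites at GR sites and 14.3% of the others were gained. Whether GR itself brings MED1 to these sites was not tested, since GR was not removed in any library used here and was called only after DEX. The enrichment reached in each library also stays open. Over the 12 MED1 libraries a random grouping is argued against for DEX, with 3182 regions at an unadjusted Fisher's exact p under 0.05 in the real split. Of 100 splits, drawn without regard to siRNA, only the real one was as large, and the highest other gave 284. This count too was chosen after the results were seen.

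GR sites no longer called with siGATA6 outnumbered gained ones, 1854 to 607. The ratio of lost to gained sites was 1.28 without siGATA6 replicate 2, so a weak library cannot be told apart from a part of this loss with 3 libraries per group. Loss at all sites where GATA6 was called is argued against at equal rank, with an odds ratio of 0.765 (0.692 to 0.844). Among the better-ranked GR sites (10 of the 20 bins), a test set after that value was seen, the ratio was 1.85 (1.07 to 3.17), an interval too wide to decide. Without ranking, 0.724% of these sites with GATA6 and 0.684% of those without were lost. Dependence of a few strong GR sites on GATA6 therefore stays open. The lost sites near HAS2 and DPYD were named by rank and not by a GATA6 site. For siGATA6 over the 12 MED1 libraries 0 regions passed adjustment in the real split and in every other split drawn. At least 377 regions had to reach the smallest Fisher's exact p of 0.00216 for it to pass, and 56 and 114 did. The planned count therefore could not speak for or against chance. The count at an unadjusted p under 0.05 was 580, reached by 3 of 100 splits with 768 in the highest other. That share is under 0.05, but this count was chosen after 0 regions had passed.

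For each comparison of 3 against 3 libraries the real split, 1 of 10, gave the most gained plus lost sites, but 10 splits are too few for a share under 0.05. The real values and the highest others were 3262 and 878 (GATA6 with DEX), 4706 and 545 (MED1 with DEX, siCtl), 3702 and 540 (siGATA6), 1368 and 669 (MED1 siGATA6, vehicle), 1706 and 599 (DEX), 2461 and 674 (GR siGATA6) and 3952 and 1016 (GR with BRM014).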
